A study of Mus musculus with 30 samples.

How the data were processed

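Nascent RNA was measured by TT-seq, in which RNA made during a short pulse of 4-thiouridine is purified and sequenced, in a mouse embryonic stem cell line that the labels call dTKO and give the genotype Suv39h1fl/fl; Suv39h2-/-; Setdb1fl/fl. Per the labels' protocols, cells grown with LIF and serum on gelatin received auxin at 100 µg/ml and dTAG13 at 0.5 µM and were collected after 0, 3, 12, 24 or 48 hours, with 3 biological repeats per time. RNA was labelled with 1 mM 4-thiouridine for 10 minutes, and 1 µg of thiouracil-labelled yeast RNA was added to 110 µg of total RNA as a spike-in, per the labels' protocols. Each library was sequenced in 2 runs, so the 30 samples in GEO are 15 libraries, and each library counted as 1 replicate.

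Per the submitters' processing notes, reads were aligned with STAR 2.5.2a to mm10 (GRCm38), and DESeq2 and deepTools were used. The deposited table lists 382367 transcription units by position, as 20541 genes, 319797 single repeat copies in 1065 families and 42029 non-coding units, of which 4145 units were at 0 in every library. Its values are signal, which the authors made as reads per unit divided by 1 size factor per library and not by length. This was checked on the values: between 99.9974% and 99.9991% of the nonzero values of a library were whole multiples of that library's smallest step, within a tolerance of 0.05, and the steps ran from 0.636 to 0.936. Multiplying back gave whole reads, called recovered reads. Whether the size factors rest on the yeast spike-in is not shown by the file. A further deposited table holds the signal that the authors averaged over the 3 libraries of a time and divided by length in kilobases, with their call of each unit as up, down or unchanged; the averages were recomputed from the values per library. The counter, its strand setting, its handling of reads with several positions and the annotation are not given in the sources used here, so near-identical paralogs, overlapping genes and single repeat copies are uncertain. Repeat copies inside a gene on the same strand were mostly absent from the table (2.5% of copies overlapped a gene on the same strand and 19.8% on the opposite strand), so a gene's value can include repeats inside it. Raw reads and the other assays of the study were not used here.

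The recovered reads over all units ran from 37.1 M (mega; 24 h replicate 3) to 42.3 M (12 h replicate 2) per library, with a median of 38.3 M. The ribosomal precursor Rn45s took between 22.5% and 30.9% of the reads in genes. The total over all units also holds non-coding units that overlap Rn45s, so reads of Rn45s may be counted in it more than once. Intervals and floors given for low counts cover counting error only.

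Genes, repeat families (the sum over all copies of 1 name), repeat copies and non-coding units were tested as separate classes. The plan, written before the data were examined, named edgeR for counts and limma for scaled values; since the values are scaled, the main test was limma 3.58.1 with the intensity trend in R 4.3.3 on log2(value + 1), with all 15 libraries in 1 fit and each later time compared with 0 h. Units with a mean of at least 10 over all libraries were tested: 15261 genes, 774 families, 13519 copies and 15730 non-coding units. A call is a Benjamini-Hochberg adjusted p under 0.05 from this two-sided limma test within the class. The fitted changes are on the log2(value + 1) scale, which can understate or overstate the changes of units with low values. The test was tried on simulated reads of all 15 libraries at their real depths, with known folds set at 48 h. Each unit took its mean over all libraries, later times included, and shifts of whole libraries were not simulated. The shares found may thus be better than in the real data. Among 15261 genes the test found 100% of the 2-fold and 4-fold rises. It found 94% of the falls to 0.5 and 100% of those to 0.25, with 9 unchanged genes called. Among 13519 copies it found 22% of the 2-fold and 100% of the 4-fold rises, 18% of the falls to 0.5 and 76% of those to 0.25, with 7 unchanged copies called, so changes of about 2-fold in single copies were mostly not detectable.

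Genes were named by a rule: those with an ordinary symbol, a call, a mean above that of the lowest-signal 25% of the tested genes and all 3 later libraries on 1 side of all 3 libraries at 0 h, ranked by change, 10 up and 10 down at 48 h and 5 up and 5 down at each other time. The rule added the targeted methyltransferases, up to 4 members of each gene list with the smallest adjusted p at 48 h, the most abundant family of each repeat group, the 5 families that rose most and the 5 that fell most at 48 h, and the 3 copies that rose most. The 20 gene lists were the targeted H3K9 methyltransferases, heterochromatin and silencing factors, naive pluripotency, 2-cell-like genes, germline genes, trophectoderm, primitive endoderm, epiblast and germ layer genes, p53 targets, interferon and RNA sensing, imprinted genes, immediate early genes, integrated stress and heat shock, aryl hydrocarbon receptor and xenobiotic genes, fibroblast feeder markers, KRAB-type and other Zfp genes, clustered protocadherins, replication-dependent histones, cytosolic ribosomal proteins, and olfactory and vomeronasal receptors. Lists were tested with limma's camera at a preset correlation of 0.01 over 80 tests, beside camera with an estimated correlation and fry. Repeat groups were formed by name: IAP, ETn/MusD, MMERVK10C, MMERVK9, RLTR13/ERVB4 with RLTR45/44, MERVL, gammaretroviral VL30 and MuLV, ERVL-MaLR, young L1, older L1, SINE B1, B2 and B4/ID, major satellite, minor satellite and structural RNA repeats. The minor satellite group held 2 families, and 613 of its 626 listed copies were MMSAT4, so its values mostly describe MMSAT4. The IAP pattern as first written missed names with a hyphen and was widened after the names were seen. Both versions of the IAP pattern were kept. The families with fewer than 3 reads were set against a floor of 3 reads over the group, about the one-sided 95% limit of a count of 0, or given as a ratio of reads with an exact 95% interval.

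Summed signal per class was compared by an exact two-sided permutation test of 3 against 3 libraries, whose smallest p is 0.1. Alternatives were a rescaling by median-of-ratios factors over genes, other additions before the log (0.1 and 5), no filter and a minimum of 50, a minimum change of 2-fold, limma without the trend, only the groups compared, a replicate block, and leaving out each library in turn. Chosen after the data were seen were edgeR 4.0.16 on recovered reads, leaving out 0 h replicate 2 and 24 h replicate 2 together, the class of non-coding units, a sum over genes without Rn45s, and counts of copies and list members with no minimum mean or with the minimum at 0 h alone. The edgeR test called 2280, 2489, 2886 and 10047 genes at 3, 12, 24 and 48 h, and 67.6% to 100% of the limma calls of a class and comparison were also called by edgeR in the same direction. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and the R package data.table (version 1.17.8), were used for sums, overlaps and plots. Gene symbols were checked against a RefSeq table (20039 current, 445 older, 57 without a match), and features near named units come from GENCODE vM21.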

Results

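Nascent transcription was followed by TT-seq in dTKO mouse embryonic stem cells, which carry the genotype label Suv39h1fl/fl; Suv39h2-/-; Setdb1fl/fl, at 0, 3, 12, 24 and 48 h after auxin and dTAG13 were added. These compounds trigger the breakdown of proteins that carry degron tags, and the study asks how loss of histone H3K9 methyltransferases alters transcription of genes, repeats and other units, with 0 h as the baseline. Each time had 3 libraries (n = 3 for every mean below), and values are reads divided by the library's deposited size factor, called scaled reads. Recovered reads per library ran from 37.1 to 42.3 M (mega) over all units. They ran from 16.4 to 22.9 M in genes without the ribosomal precursor Rn45s and from 0.837 to 2.06 M in repeat copies. Non-coding units that do not overlap Rn45s held 4.29 to 5.37 M. The total over all units also holds the non-coding units that overlap Rn45s, so reads of Rn45s may be counted there more than once. Coordinates are mm10, and each gene named for the size of its change at a time had all 3 later libraries on 1 side of all 3 libraries at 0 h.

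Transcription of Setdb1, Suv39h1 and Suv39h2, the methyltransferase genes that the genotype label names, was examined first. The label names no degron tags, so which proteins the compounds remove is not given in the sources used here. Setdb1 (chromosome 3, 95323525-95357202) gave 846 ± 24.9 scaled reads (SD) at 0 h and 732 ± 46.3 at 48 h, a log2 change of -0.21 (SE 0.13) that did not pass. Suv39h1 (chromosome X, 8061171-8074760) gave 483 ± 36.3 and 455 ± 23.4, a log2 change of -0.09 that did not pass. Suv39h2 (chromosome 2, 3455815-3474986) decreased from 1091 ± 72.9 to 803 ± 69.4, a log2 change of -0.44 (limma adjusted p 0.0011), which was -0.08 after rescaling over genes and no longer passed. At 12 h Setdb1 was higher by 0.34 (limma adjusted p 0.0463) and Suv39h1 by 0.36 (limma adjusted p 0.041); neither call held without 0 h replicate 1 (limma adjusted p 0.15 and 0.222), 0 h replicate 3 (0.184 and 0.144), 12 h replicate 2 (0.274 and 0.228) or 12 h replicate 3 (0.18 and 0.135), and that of Setdb1 was also lost without 0 h replicate 2 (0.07). After rescaling, the 48 h changes of Setdb1 and Suv39h1 flipped to 0.15 and 0.28. The compounds act on protein, so transcript levels do not check the time labels. Suv39h2 still gave 1091 scaled reads at 0 h although its label reads -/-, and the table does not show which part of the gene these reads fall in.

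Repeat families were compared with 0 h to ask which repeats gained nascent transcription and when. MMERVK10C-int, the internal part of a class II endogenous retrovirus, rose from 3 h on: its summed signal was 9157 ± 460 scaled reads at 0 h, 24820 ± 5153 at 3 h, 135600 ± 18450 at 12 h, 299900 ± 49680 at 24 h and 494700 ± 25520 at 48 h, a log2 rise of 5.76 (SE 0.12). Its LTR RLTR10C rose by 1.18, 3.49, 4.45 and 5.05 at the 4 times. IAPEz-int was at 4812 ± 139 at 0 h and 4969 ± 475 at 3 h, then rose to 13340 ± 1337, 45600 ± 4740 and 80150 ± 4727, a log2 change of 4.06 at 48 h; its 3 h change of 0.04 became a call of 0.28 after rescaling. MERVL-int, from a retrovirus active in 2-cell embryos, rose late, by 0.66 at 12 h, 1.33 at 24 h and 3.06 at 48 h (2322 ± 198 to 19320 ± 1346). The pericentromeric major satellite GSAT_MM followed a like course, by 0.66, 1.94 and 3.23 (1175 ± 63.7 to 11040 ± 497). In limma, 12 families were called up and 15 down at 3 h, 255 and 3 at 12 h, 189 and 8 at 24 h, and 181 and 38 at 48 h, of 774 tested. After rescaling the splits were 39 and 1, 213 and 12, 305 and 11, and 499 and 11. The 27 families called at 3 h became 135 (12 up, 123 down) with only the groups compared, 13 without the trend, 14 without 0 h replicate 1, 11 without 0 h replicate 2, 11 without 0 h replicate 3, 10 without 3 h replicate 1 and 12 without 3 h replicate 2, and the 258 at 12 h became 163 without 12 h replicate 2.

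**Figure D1:**
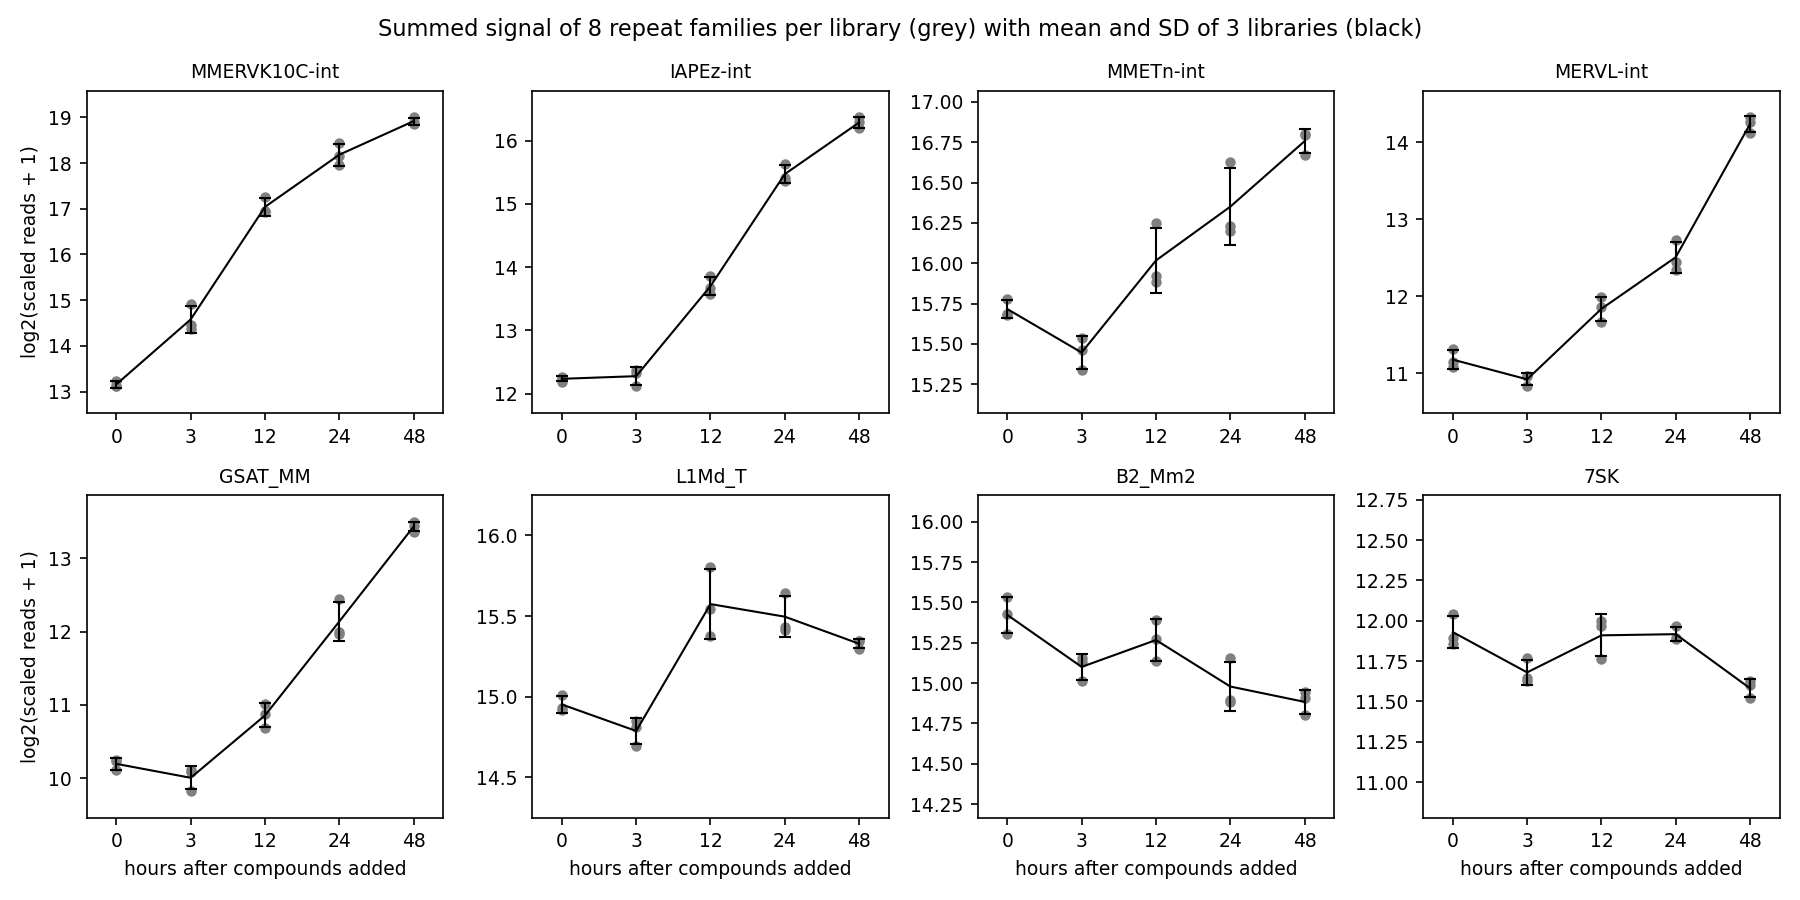
Summed signal of 8 repeat families, as log2(scaled reads + 1) on the y axis against hours after the compounds were added on the x axis, with each library in grey and the mean and SD of 3 libraries in black. MMERVK10C-int is above its 0 h level from 3 h on, while MERVL-int rises most between 24 and 48 h.

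At 48 h MMERVK9C_I-int was higher by 1.58 (SE 0.12), RLTR1B-int by 1.39, RLTR13G by 1.15 and MMETn-int by 1.04 (53860 ± 2138 to 110800 ± 5651). The median changes of their tested copies, which the minimum mean favours when they rise, were 3.35 (71 copies), 1.71 (91), 2.33 (58) and 3.41 (272). The 12 h rise of RLTR13G (0.43) did not pass without 12 h replicate 2 (limma adjusted p 0.0606). That of MMETn-int (0.30) did not pass after rescaling (0.12), or without 0 h replicate 1 (limma adjusted p 0.123), 0 h replicate 3 (0.116) or 12 h replicate 2 (0.294). ERVB4_1B-I_MM-int rose from 58.9 ± 9.15 to 1260 ± 41.5 scaled reads at 48 h (4.41, SE 0.14). RLTR47_MM had no reads at 0 h and was at least 29.4-fold higher at 48 h against a floor of 3 reads over the group (two-sided exact 95% lower limit 23.5), and X5A_LINE had 2 reads at 0 h, a ratio of 61.9 (exact 95% interval 16.8 to 516). The retrotransposon L1Md_T was higher by 0.62 at 12 h and 0.38 at 48 h (31700 ± 1130 to 41150 ± 752), while Lx8 did not pass at 48 h (0.23, and 0.60 with a call after rescaling). B2_Mm2 fell by 0.54 at 48 h (44010 ± 3431 to 30260 ± 1568), and by 0.17 after rescaling. B1_Mus1 was at -0.37 with a call and at -0.01 without one after rescaling. ORR1A2 (-0.20), ID_B1 (-0.23) and MMSAT4 (-0.17) did not pass and flipped to 0.17, 0.14 and 0.20 after rescaling; 7SK was at -0.35 with a call, flipped to 0.01 after rescaling, and lost the call without 0 h replicate 3 (limma adjusted p 0.119) or 48 h replicate 1 (0.0834). The families that fell most at 48 h held few reads, with MER99 down from 16.7 ± 3.65 to 6.08 ± 1.36 (-1.32), then RLTR20C (-1.16), MER34-int (-1.14), L1M6 (-1.02) and RMER16B2 (-0.86). The call of L1M6 was lost without 0 h replicate 1 (limma adjusted p 0.0616), 0 h replicate 2 (0.0734) or 48 h replicate 1 (0.0936).

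Single copies were counted in each group. A copy silent at 0 h could reach the minimum mean for testing only by rising, so shares among tested copies overstate how widely a group rose. Of 878 tested MMERVK10C copies, 260 rose at 3 h, 732 at 12 h, 822 at 24 h and 826 at 48 h, when 5 fell and the median log2 change was 5.77. IAP copies rose later, 18, 449, 766 and 791 of 913, with 11 lower at 48 h, and ETn/MusD copies 11, 324, 474 and 515 of 636, with 17 lower at 48 h. MERVL copies were called up in 2, 37, 94 and 173 of 233 cases, and 12 of 13 major satellite copies rose at 48 h. Without the minimum, 1587 of 4839 MMERVK10C copies (32.8%), 3461 of 9589 IAP (36.1%), 1018 of 2563 ETn/MusD (39.7%) and 1138 of 3077 MERVL copies (37%) rose at 48 h, and among copies with a mean of at least 10 at 0 h 142 of 189, 47 of 158, 164 of 280 and 28 of 84 did. At 48 h 94 of 148 MMERVK9 copies, 126 of 195 RLTR13/ERVB4 and RLTR45/44 copies and 142 of 266 VL30 and MuLV copies rose, and 8, 15 and 14 fell. With the minimum at 0 h alone 19 of 74, 28 of 101 and 47 of 162 rose, and 8, 13 and 12 fell. Young L1 copies rose in 291 of 1117 cases at 12 h and 232 at 48 h, when 43 fell. With the minimum at 0 h alone 68 of 820 young L1 copies rose and 48 fell at 48 h. Of 2188 SINE B2 copies 686 fell and 49 rose at 48 h. SINE B1 had 46 rises and 270 falls among 1698 copies at 48 h, SINE B4/ID 37 and 83 among 925, and ERVL-MaLR 78 and 129 among 1068. Older L1 had 75 and 69 among 655. The split for older L1 was 21 and 64 among 643 with the minimum at 0 h alone, and 715 and 89 among 25503 without the minimum. Minor satellite, mostly MMSAT4, had 5 and 13 among 189. None of the 3 copies of 7SK, the structural RNA family tested, passed. Over all 13519 tested copies limma called 338 up and 36 down at 3 h, 2813 and 248 at 12 h, 3437 and 845 at 24 h, and 3515 and 1660 at 48 h. With only the libraries of the groups compared, the 3 h calls were 8 up and 3 down. After rescaling the counts were 473 and 15, 2514 and 538, 3670 and 776, and 4239 and 717. Reads of near-identical copies can be assigned to the wrong copy, and how reads with several positions were counted is not given in the sources used here.

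The 3 copies that rose most at 48 h were all MMERVK10C-int. The copy on chromosome 5 (15000001-15004545, minus strand, overlapping no annotated gene) went from 2.99 ± 3.84 to 6198 ± 382 scaled reads, a log2 rise of 11.11 (SE 0.57, limma adjusted p 7.06e-10). The copy on chromosome 8 (4682432-4687356, minus strand) had no reads at 0 h, 35 ± 41.6 scaled reads at 3 h and 2190 ± 86.0 at 48 h, at least 2630-fold higher at 48 h against a floor of 3 reads over the group (two-sided exact 95% lower limit 2130). It lies within the lincRNA Gm6410 on the opposite strand and overlaps none of its exons. The copy on chromosome 19 (8244056-8248998, plus strand) went from 2.57 ± 4.46 to 2534 ± 157, a log2 rise of 10.27 (SE 0.73, limma adjusted p 1.94e-08), and the nearest protein-coding gene, Slc22a29, is 25156 bp away.

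At 3 h the genes that rose most included xenobiotic response genes. Cyp1b1 (chromosome 17, 79706953-79715041), a cytochrome P450 gene, rose from 35.9 ± 4.60 to 222 ± 8.35 scaled reads, a log2 change of 2.60 (SE 0.16, limma adjusted p 4.76e-56). Cyp1a1, which the list of aryl hydrocarbon receptor genes names, rose from 6.09 ± 1.59 to 134 ± 5.35 (4.28, SE 0.24), and Ahrr (1.61) and Tiparp (0.67) of that list rose too. Clec2f (2.30), Mmp1b (1.96), Bglap3 (1.86) and Rdh16 (1.75) also rose; Rdh16 had 2 reads at 0 h, a ratio of 7.46 (exact 95% interval 1.79 to 66.3). The growth factor gene Fgf5 fell from 299 ± 17.9 to 136 ± 17.5 (-1.14, SE 0.15), followed by Enpp2 (-0.95), Edn1 (-0.94), Kynu (-0.92) and Bcl11a (-0.90); after rescaling these were -0.90, -0.72, -0.70, -0.69 and -0.67. In limma, 97 genes were called up and 2053 down of 15261, around a median log2 change of -0.24, and 760 up and 1241 down after rescaling. At least 2-fold changes with a call numbered 31 up and 26 down. The total of 2150 became 6119 (94 up, 6025 down) with only the groups compared, 3230 (104 up, 3126 down) with a replicate block and 1263 without the trend. It became 1307 without 0 h replicate 1, 470 without 0 h replicate 2, 1167 without 0 h replicate 3, 911 without 3 h replicate 1 and 489 without 3 h replicate 2.

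At 12 h Clec2f, a C-type lectin-like receptor gene, rose most, from 3.05 ± 0.416 to 353 ± 62.9 scaled reads (6.44, SE 0.15). Mmp1b (5.42), Clec2g (4.91), Rdh16 (4.75) and Vmn2r96 (4.62) followed, the last with 1 read at 0 h, a ratio of 106 (exact 95% interval 18.6 to 4240). The ratio for Rdh16 was 74.1 (20.1 to 618). Fgf5 fell by 1.67, Enpp2 by 1.52, Mecom by 1.06 and both Itga10 and Egfl6 by 1.03. In limma, 1972 genes were called up and 316 down around a median of 0.18, and 2407 up and 2270 down after rescaling, so the balance of rises and falls depended on the scaling. At least 2-fold changes numbered 348 up and 37 down. The 2288 calls became 1221 without 0 h replicate 1, 1252 without 0 h replicate 3, 5547 without 12 h replicate 1, 1194 without 12 h replicate 2 and 1342 without 12 h replicate 3.

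At 24 h Clec2f reached 598 ± 106 scaled reads (7.20), Clec2g 1892 ± 224 (6.49), Cd209c 343 ± 47.7 (6.54) and Mmp1b 371 ± 53.7 (6.37), and Vmn2r96 reached 185 ± 49.4, a ratio of 662 (exact 95% interval 118 to 26200). Enpp2, the autotaxin gene, fell from 363 ± 17.3 to 57.8 ± 22.1 (-2.69, SE 0.15), followed by Fam196b (-2.37), Aoah (-2.09), Fgf5 (-1.86) and Egfl6 (-1.83). In limma, 1101 genes were called up and 1859 down around a median of -0.08, and 3306 up and 3332 down after rescaling. At least 2-fold changes numbered 425 up and 320 down, and the 2960 calls became 4938 without 24 h replicate 2.

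At 48 h Clec2f (chromosome 6, 129014112-129020527) rose from 3.05 ± 0.416 to 622 ± 36.2 scaled reads (7.27, SE 0.15), Cd209c (chromosome 8, 3940222-3946863) from 2.76 ± 0.910 to 773 ± 34.4 (7.71, SE 0.17) and Clec2g (chromosome 6, 128934381-128984707) from 20.0 ± 1.84 to 2686 ± 253 (7.0, SE 0.13). Mmp1b (6.87), the organic anion transporter gene Slc22a13 (6.23), Nat8f2 (6.12), Poteg (5.79) and the 2-cell-stage gene Zscan4b (5.78) followed. Vmn2r96 had 1 read at 0 h, a ratio of 1360 (exact 95% interval 243 to 53600), and the retinol dehydrogenase gene Rdh16 had 2, a ratio of 378 (104 to 3130). Aoah (chromosome 13, 20794113-21024254) fell from 1302 ± 104 to 116 ± 3.15 (-3.48, SE 0.13), and Fam196b (-3.29), Rasgrp1 (-3.11), the hedgehog pathway factor gene Gli1 (-2.93), the hormone precursor gene Trh (-2.87), Mcf2 (-2.69), Inhbb (-2.48), Enpp2 (-2.38), Sytl3 (-2.36) and Stk33 (-2.33) followed. All 20 of these changes kept their sign and call after rescaling and without each library in turn. In limma, 1167 genes were called up and 8905 down of 15261, around a median of -0.37, and 4544 up and 4428 down after rescaling. At least 2-fold changes numbered 463 up and 992 down. Clec2, Vmn2r, Nat8f and Zscan4 genes have near-identical paralogs, so their single values are uncertain.

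**Figure D2:**
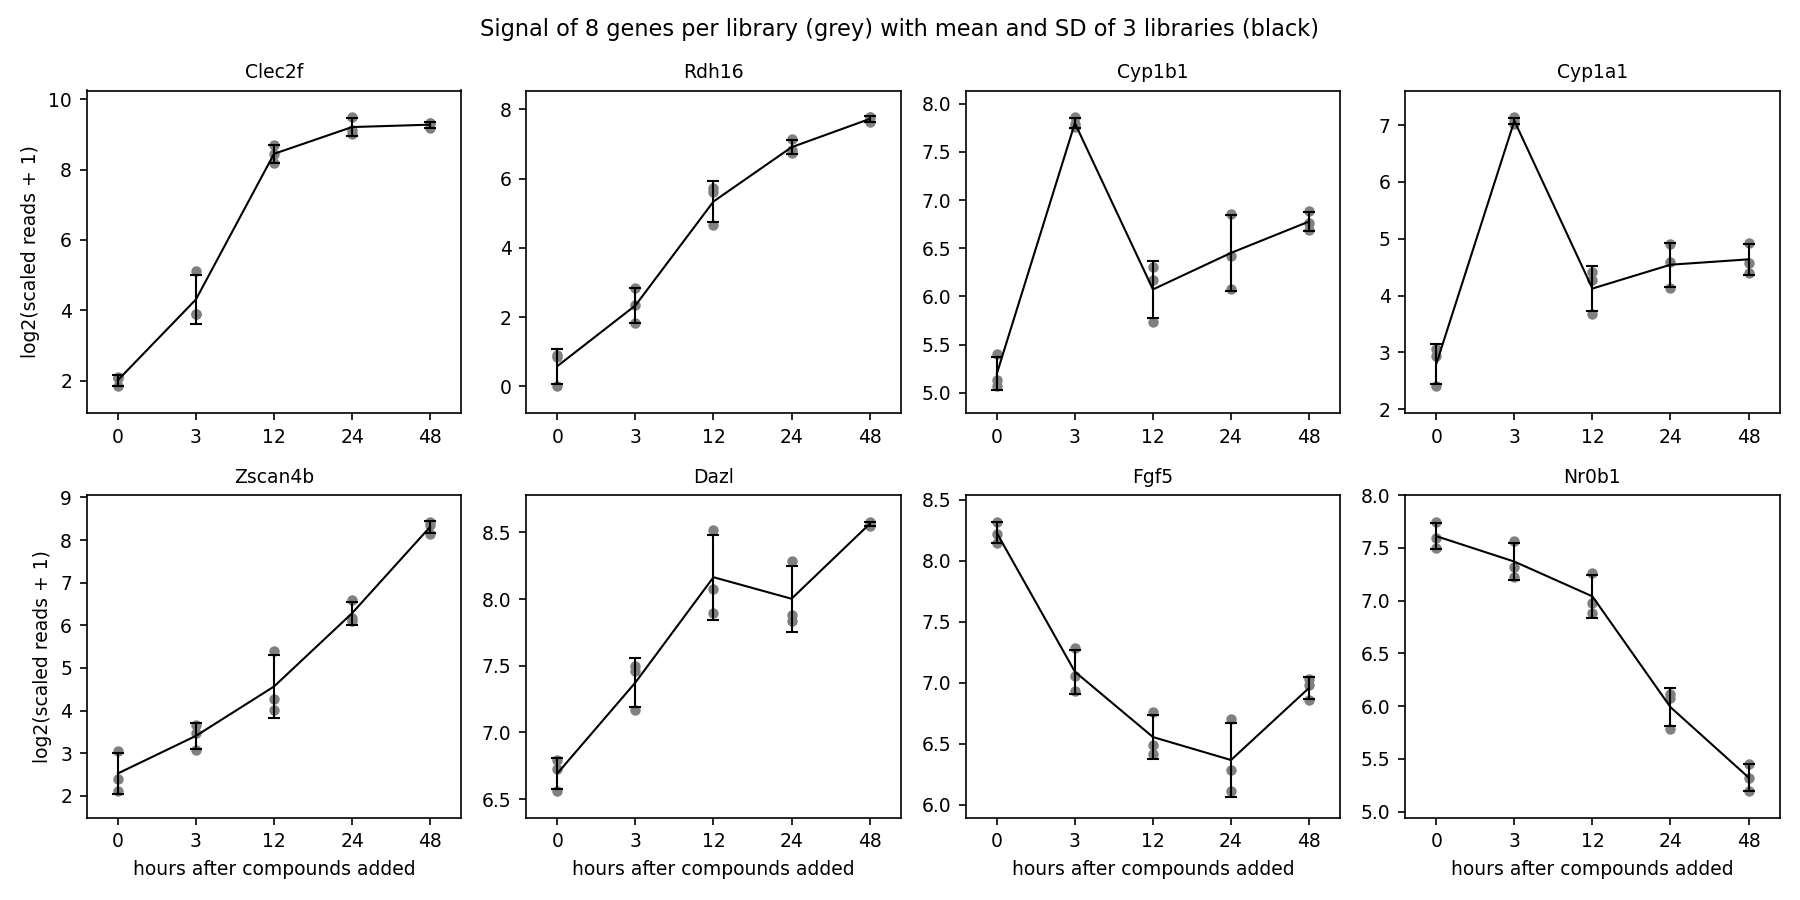
Signal of 8 genes, as log2(scaled reads + 1) on the y axis against hours after the compounds were added on the x axis, with each library in grey and the mean and SD of 3 libraries in black. Cyp1b1 and Cyp1a1 peak at 3 h, while Clec2f, Rdh16 and Zscan4b rise over the course and Nr0b1 falls.

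**Figure D3:**
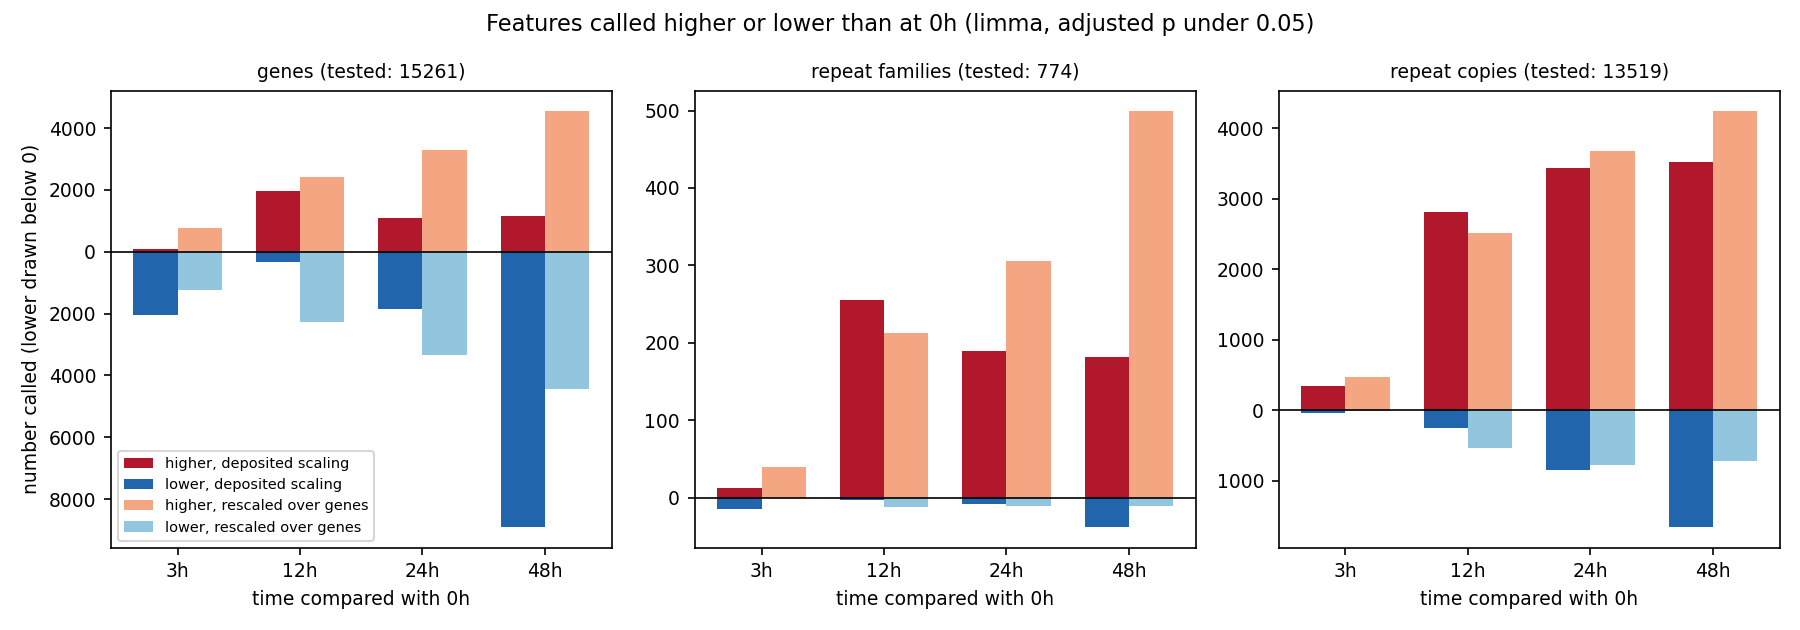
Number of genes, repeat families and repeat copies called up (above 0) or down (below 0) by limma at each time against 0 h, with dark bars for the deposited scaling and light bars after rescaling over genes. At 48 h 1167 genes were up and 8905 down with the deposited scaling, and 4544 and 4428 after rescaling.

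Gene lists fixed in advance asked which programmes moved, and 2-cell-like genes moved furthest. Of 18 measured members of 34 listed, 3 rose and 1 fell at 3 h, 12 rose at 12 h, and all 18 rose at 24 and 48 h, with a median log2 change of 4.11 at 48 h; adjusted over the list alone the counts were 3 and 1, 14, 18 and 18, and after rescaling 3, 11, 18 and 18 rose and none fell. Without the minimum mean 31 of 34 rose at 48 h, as did all 6 with a mean of at least 10 at 0 h. Zscan4f rose from 14.2 ± 2.26 to 569 ± 82.1 (5.23, SE 0.17), Zscan4d by 4.95, Zscan4c by 5.55 and Zfp352 by 5.26. Of 25 measured olfactory and vomeronasal receptor genes of 251 listed, 3 rose at 3 h, 18 at 12 h, 18 at 24 h and 19 at 48 h, with 1 lower at 24 h and 3 at 48 h (adjusted over the list alone 3, 18, 20 and 19 rose, and 1, 1, 1 and 3 fell; after rescaling 4, 17, 20 and 20 rose, and 0, 1, 1 and 3 fell). Receptor genes silent at 0 h were measured only if they rose: without the minimum mean 76 of 249 rose at 48 h, and of 14 with a mean of at least 10 at 0 h 6 did. Vmn2r36 (4.80) and Vmn2r60 (4.24) rose, as did Vmn2r22, with 1 read at 0 h and a ratio of 335 (exact 95% interval 59.7 to 13300). Of 12 measured aryl hydrocarbon receptor and xenobiotic genes, 4 rose and 1, Ahr (-0.43), fell at 3 h (5 and 2 adjusted over the list alone), 5 rose at 12 h, 2 rose and 1 fell at 24 h, and 2 rose and 7 fell at 48 h, among them Gstm1 (-0.85) and Gclm (-0.58); after rescaling the splits were 8 and 1, 4 and 2, 2 and 4, and 4 and 3. Limma's camera, which compares a list with all other genes, gave an adjusted p of 2.01e-08, 9.85e-11, 3.31e-34 and 5.23e-80 for the 2-cell-like list at the 4 times, 2.7e-43 for the aryl hydrocarbon receptor list at 3 h and 1.06e-09, 8.67e-16, 4.46e-30 and 7.19e-31 for the receptor list. With an estimated correlation the limma adjusted p values were 0.043, 0.0204, 0.000624 and 2.41e-05, then 0.0048, and then 0.0523, 0.0145, 0.0017 and 0.0017, so that of the receptor list at 3 h was lost. These 8 were the calls that held with an estimated correlation among the 34 of 80 that passed at the preset one. After rescaling, camera no longer called the 2-cell-like list (limma adjusted p 0.0854) or the receptor list (limma adjusted p 0.0512) at 3 h, where the receptor list's median was -0.06 and its mean 0.02. With the minimum mean applied at 0 h alone, the 2-cell-like call at 3 h (limma adjusted p 0.212) and the receptor call at 12 h (limma adjusted p 0.198, and 0.266 without the minimum) were lost, and the receptor list at 48 h had a limma adjusted p of 0.00487.

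Most naive pluripotency genes fell by 48 h, and germline genes rose in part. Of 24 naive pluripotency genes, 16 fell at 3 h, 4 at 12 h, 16 at 24 h and 21 at 48 h, when Zfp42 (0.85) rose and 2 did not pass (21 and 1 adjusted over the list alone). After rescaling 13, 21, 20 and 17 fell and 1, 1, 1 and 4 rose at the 4 times, so the dip in calls at 12 h came with the deposited scaling only. At 48 h Nr0b1 fell from 195 ± 17.3 to 39.2 ± 3.60 (-2.29, SE 0.15), Fgf4 by 1.75, Tet2 by 1.44, Tfcp2l1 by 1.09 and Pou5f1 by 1.08, around a list median of -0.77. Camera in limma called the list down at all 4 times (adjusted p 1.42e-05, 7.96e-05, 2.89e-05 and 7.8e-05), and every call was lost with an estimated correlation (adjusted p 0.999 each). Of 37 measured germline genes, 12 rose at 3 h, 25 at 12 h, 18 at 24 h and 18 at 48 h, when 11 fell (18 and 11 adjusted over the list alone). After rescaling 21, 26, 23 and 23 rose and 0, 0, 4 and 8 fell. Dazl rose from 103 ± 8.39 to 377 ± 3.75 at 48 h (1.87, SE 0.14), Slc22a16 by 2.18, Stk31 by 1.48 and Mael by 1.46, while Rpl10l fell by 0.93. Camera in limma gave adjusted p 1.81e-33, 2.77e-25, 3.54e-10 and 1.06e-09, all lost with an estimated correlation (adjusted p 0.0877, 0.166, 0.78 and 0.782).

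Interferon genes did not rise as a list. Of 25 measured interferon and RNA sensing genes, 18 fell and none rose at 48 h (the same adjusted over the list alone; 15 fell and 2 rose after rescaling), among them Ifitm1 (262 ± 11.4 to 83.1 ± 10.5, -1.65), Oas1g (-1.32), Ifitm3 (-1.15) and Mavs (-0.89). Camera in limma did not call the list at 48 h (adjusted p 0.0781, and 0.0131 after rescaling), while fry, which asks whether the genes moved on balance 1 way, gave an adjusted p of 0.000268. Fry does not set a list against the other genes, and the median over all genes was -0.37. It also passed for the ribosomal list (fry adjusted p 0.0257), which camera did not call. At 12 h 3 interferon and RNA sensing genes fell, with a camera call down in limma (adjusted p 0.0437). That call was lost with an estimated correlation (adjusted p 0.999) and stood beside a list median of 0.05. Of 29 heterochromatin and silencing factor genes, 25 fell at 48 h, among them Ehmt2 (-0.71), Trim28 (-0.66), Cbx1 (-0.64) and Mphosph8 (-0.55), with 25 adjusted over the list alone and, after rescaling, 11 down and 4 up. Of 23 stress genes, 16 fell and none rose at 48 h, by either adjustment, with Nupr1 (-1.51), Slc7a11 (-1.22), Trib3 (-0.81) and Hsph1 (-0.71), and 10 fell and 6 rose after rescaling. Camera in limma did not call these 2 lists at 48 h (adjusted p 0.321 and 0.429).

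Lineage lists were mixed at 48 h. Of 16 trophectoderm genes 5 rose, among them Krt18 (1.00), Peg10 (0.86) and Krt8 (0.71), and 5 fell, among them Eomes (-1.19), with 8 and 1 after rescaling, a median of -0.07 and a mean of 0.07. Of 21 immediate early genes 8 rose and 5 fell (13 and 3 after rescaling), with Atf3 (1.26), Klf6 (0.76) and Zfp36 (0.76) higher and Spry4 (-0.89) lower. Of 17 fibroblast feeder markers 9 rose and 4 fell (11 and 2 after rescaling), with Lum at 3.05, Col5a2 at 1.41, Loxl1 at -0.85 and Thy1 at -2.23. Of 30 clustered protocadherins 8 rose, among them Pcdha3 (1.56), Pcdha6 (1.75), Pcdha7 (1.70) and Pcdha8 (1.81), whose units overlap and share exons, and 15 fell (10 and 0 after rescaling), with a median of -0.34 and a mean of 0.18. Adjusted over the list alone the counts of these 4 lists were the same. Camera in limma called all 4 up (adjusted p 0.0192, 0.00601, 0.00102 and 0.0234), and all were lost with an estimated correlation (adjusted p 0.999, 0.999, 0.855 and 0.999); after rescaling the protocadherin call was lost too (adjusted p 0.122). The protocadherins were also called at 24 h in limma (adjusted p 0.00949, and 0.999 with an estimated correlation). Of 36 listed protocadherins 30 were measured, and a member silent at 0 h was measured only if it rose, which favours a call up at both times.

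Lists without a camera call at 48 h also held called genes. Of 15 primitive endoderm genes 2 rose and 5 fell (9 and 4 after rescaling), with Hnf4a (-2.07), Lama1 (-1.72), Cubn (-1.32) and Sox7 (-1.29) lower; of 19 epiblast and germ layer genes 3 rose and 7 fell (8 and 4), with Pax3 (0.79) and Otx2 (0.77) higher and Fgf5 (-1.27) and Nodal (-0.74) lower; and of 29 p53 targets 5 rose and 11 fell (18 and 4), with Cd80 (-1.48), Gdf15 (-1.43), Ptp4a3 (-0.65) and Aen (-0.49) lower. Of 36 imprinted genes 5 rose and 22 fell (9 and 10), with Igf2 (1.30), Peg10 and Inpp5f (0.86 each) higher and Plagl1 (-0.80) lower. Adjusted over the list alone, these 4 lists had 2 and 5, 3 and 7, 5 and 10, and 5 and 23. Of 345 Zfp genes 22 rose and 189 fell (22 and 187 adjusted over the list alone, 120 and 79 after rescaling), with Zfp37 (1.89), Zfp677 (1.37) and Zfp560 (1.22) higher. Of 65 replication-dependent histone genes 21 fell and none rose (14 adjusted over the list alone, but 31 up and 5 down after rescaling), with Hist1h1t (-1.70), Hist2h2be (-0.76), Hist1h2bh (-0.72) and Hist1h2af (-0.67) lower. Of 84 cytosolic ribosomal protein genes 1 rose and 67 fell (1 and 71 adjusted over the list alone, 18 and 11 after rescaling), with Rpl13a (-0.67), Rpl22 (-0.54) and Rps29 (-0.51) lower. Camera in limma gave adjusted p 0.741, 0.271, 0.438, 0.648, 0.866, 0.732 and 0.438 for these 7 lists, and 0.972 for the list of Setdb1, Suv39h1 and Suv39h2; after rescaling it called the p53 (adjusted p 0.0087) and histone (adjusted p 0.0426) lists up. The camera direction was up beside a negative median and a negative mean for all of them except the ribosomal list. Camera compares mean test statistics of a list with those of the other genes, and the median over all genes was -0.37. A direction of up therefore does not mean that a list rose.

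At the early times the limma camera test also called other lists. At 3 h it called the heterochromatin (adjusted p 0.0054), trophectoderm (0.00102), primitive endoderm (0.00197), epiblast (2.02e-07), p53 (0.006), imprinted (0.00463), immediate early (0.00863) and feeder (0.026) lists down and the stress list (0.000284) up, the last with a negative median (-0.14). At 12 h it called the epiblast (0.00818) and histone (9.45e-06) lists down. All of these were lost with an estimated correlation, where the limma adjusted p was 0.859 for trophectoderm, 0.541 for epiblast at 3 h and 0.999 for the others. After rescaling, camera in limma also called the Zfp (adjusted p 0.0131) and ribosomal (0.0136) lists up at 3 h and, at 12 h, the primitive endoderm (0.0195) and p53 (0.00255) lists down and the protocadherins (0.00525) up. The interferon call at 12 h was then lost (0.0989). Genes behind the 3 h falls included Otx2 (-0.85), Spry4 (-0.73) and Igf2 (-0.61).

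The last interval was tested directly to ask what still changed between 24 and 48 h. MERVL-int rose by a further 1.73, GSAT_MM by 1.29, IAPEz-int by 0.82 and MMERVK10C-int by 0.73. Zscan4f (2.14), Zscan4d (2.07) and Zfp352 (2.80) rose, while Gli1 fell by 1.81 and Rasgrp1 by 1.68. In limma, 367 genes were called up and 6202 down around a median of -0.28 (3358 and 2544 after rescaling), with 100 up and 100 down at least 2-fold, and 31 families were called up and 3 down (331 and 0 after rescaling). The 6569 genes became 3362 without 24 h replicate 2 and 3224 without 48 h replicate 1, and the 34 families became 53 without 24 h replicate 2 and 22 without 24 h replicate 3. Over the whole course the limma F test called 13812 of 15261 genes.

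Summed signal showed how much of the output repeats made up. All repeat copies together gave 726 ± 36.3 k scaled reads (k, kilo) at 0 h and 1529 ± 63.9 k at 48 h, 0.867-, 1.42-, 1.71- and 2.11-fold at the 4 times. MMERVK10C sums were 2.41, 12.5, 27.1 and 44.5 times those at 0 h, IAP sums 1.07, 2.58, 7.12 and 12 times, and at 48 h the major satellite reached 9.4, MERVL 6.33, the RLTR13/ERVB4 group 3.3, MMERVK9 2.74, ETn/MusD 2.57, VL30 and MuLV 2.52, young L1 1.31 and older L1 1.18 times. With the IAP group as first written, the 48 h ratio was 6.5. At 48 h ERVL-MaLR was at 0.974, minor satellite at 0.894, SINE B4/ID at 0.864 and SINE B1 at 0.803 of the 0 h sum. Structural RNA was at 0.785 and SINE B2 at 0.696 of it. After rescaling all of these but SINE B2 lay above the 0 h sum. The minor satellite sum is mostly MMSAT4, and the other family of that group was called up at 48 h, by a log2 change of 1.10. Genes summed to 22070 ± 772 k at 0 h and 18220 ± 550 k at 48 h, 0.826-fold (0.814-fold without Rn45s), a log2 ratio of -0.28 that became 0.09 after rescaling. Each comparison of 3 against 3 libraries has a smallest exact two-sided permutation p of 0.1 (0.131 after Benjamini-Hochberg adjustment), so none could pass 0.05. Without the 10 families with the highest mean, the log2 ratio of all repeat copies at 48 h was 0.47 in place of 1.08.

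Early calls were compared with late ones. Of the 97 genes up at 3 h, 93 were also up at 12 h, where independent lists would share 12.5, and of 1101 up at 24 h, 828 were up at 48 h (84.2 for independent lists). Of those 97, 87 were up at 48 h (7.4). Of 316 genes down at 12 h, 295 were down at 24 h (38.5), and of 1859 down at 24 h, 1772 were down at 48 h (1085). Of 2053 genes down at 3 h, 223 were down at 12 h (42.5) and 1324 at 48 h (1198), and of 1972 up at 12 h, 908 were up at 24 h (142). All 338 copies up at 3 h were up at 12 h (70.3), 3227 of 3437 up at 24 h were up at 48 h (894), and 170 of 189 families up at 24 h were up at 48 h (44.2). Simulated unchanged groups against the same controls shared 0 in each case, which carries little weight, since unchanged groups give few calls to share. Across genes, which are not independent replicates, the 24 h and 48 h changes had r 0.9 and covariance 0.338, against 0.5 and 0.0139 in the simulation, and across copies r 0.975 and covariance 4.63 against 0.503 and 0.114. The 3 h and 48 h changes of genes had r 0.427 and covariance 0.0618, against 0.5 and 0.0139 in the simulation. The 3 control libraries are too few to split, and an unknown part of each excess comes from sharing them.

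Genes that rose were located against LTR copies that rose, to ask whether the 2 lie together. Nat8f2 (chromosome 6, 85865422-85869137, minus strand) starts 67 bp from an ERVB7_2B-LTR_MM copy that rose by 5.28, and Slc22a13 (chromosome 9, 119192978-119209105, minus strand) 476 bp from an RLTR10E copy that rose by 5.13 and lies within Slc22a14, outside its exons. An MMERVK10C-int copy (chromosome 8, 3946329-3951359, minus strand) that rose by 6.75 covers the start of Cd209c and overlaps an exon. Rdh16 lies 6778 bp from an IAPEY3-int copy that is nearer to Rdh9 (53 bp, same strand), and Vmn2r96 lies 15502 bp from an IAPLTR3-int copy, while for Zscan4b the nearest was at 64133 bp and for Cyp1b1 at 1139257 bp. Among 463 genes called up at least 2-fold at 48 h, 92 (19.9%) started within 20000 bp of a raised LTR copy, against 333 (2.3%) of 14798 other tested genes. The odds ratio was 10.8 (95% interval 8.27 to 13.9; Fisher's exact test, two-sided, p 5.81e-53, adjusted p 2.32e-52 over 8 such tests). Among the 992 genes called down at least 2-fold it was 0.447. Fisher's test treats genes as independent, while neighbouring genes can share a raised copy, so these intervals and p values may be too narrow. Reads running from a copy into a gene are counted in both where the strand is the same, and the strand setting is not given in the sources used here.

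**Figure D4:**
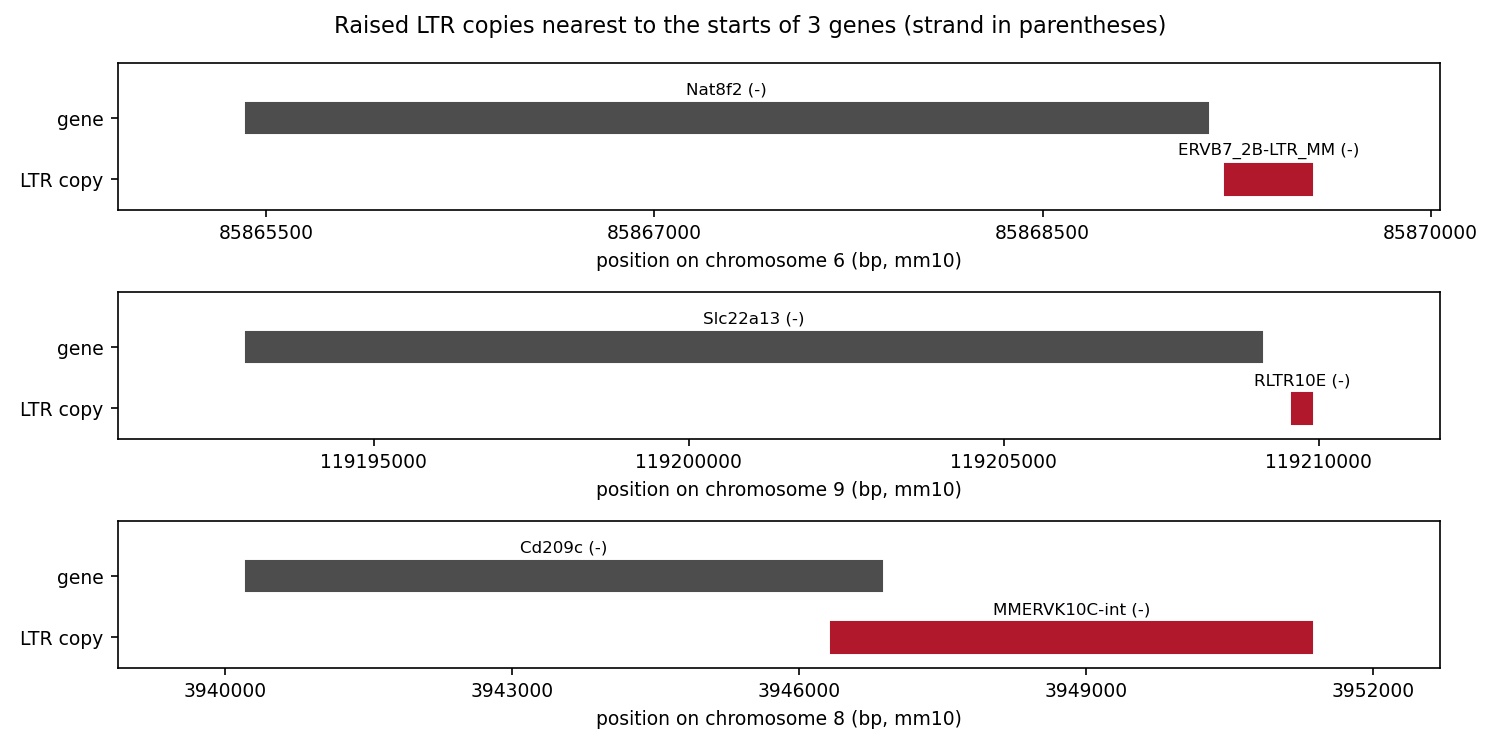
Position of Nat8f2, Slc22a13 and Cd209c (grey) and of the raised LTR copy nearest to the start of each (red) along the chromosome in bp (mm10), with the strand in parentheses. The copies lie 67 bp and 476 bp from the first 2 genes and cover the start of Cd209c.

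Non-coding units, a class added after the data were seen, were called in both directions. Of 15730 tested units limma called 1217 up and 1268 down at 3 h, 4617 and 1748 at 12 h, 4781 and 3900 at 24 h, and 4613 and 6195 at 48 h; after rescaling these were 1730 and 297, 4211 and 3436, 5208 and 3600, and 5621 and 3456. Of the 3987 units up at least 2-fold at 48 h, 3009 (75.5%) overlapped an LTR copy, against 503 (20.4%) of the 2462 down at least 2-fold and 2364 (25.5%) of the other 9281. A raised LTR copy was overlapped by 1125 (28.2%), 10 (0.4%) and 91 (1%) of them. Reads in a unit and a copy that overlap may be counted in both, and 7.2% of listed copies overlapped a non-coding unit on the same strand. Units and copies silent at 0 h were also tested only if they rose. These shares therefore do not show that units and copies rose independently of each other. The deposited calls of the authors at 48 h were 571 genes up and 1031 down. All 445 up and 964 down that were tested here were called in the same direction, as were 16 up and 4 down at 3 h. Of the authors' 418 repeat copies up at 3 h, 287 were called up here, and of 26 down, 3 were called down.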

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

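Of the tests in this part, the one on the share of reads in genes was chosen only after the result was seen. Effects at 48 h and at 24 h were set against each other in a two-sided limma test of the difference itself, and an item is given here when that difference passed under both the deposited scaling and the rescaling over genes with the same sign. This held for 59 of 128 named items, 33 higher and 26 lower at 48 h, 16 of them at least 2-fold; values below are log2 changes from 24 h to 48 h.

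In the last interval MERVL-int rose by 1.73, GSAT_MM by 1.29, IAPEz-int by 0.82, MMERVK10C-int by 0.73, RLTR10C by 0.61, ERVB4_1B-I_MM-int by 0.58 and MMETn-int by 0.41. Other families did not pass under the deposited scaling, among them MMERVK9C_I-int (0.10), RLTR1B-int (0.05), RLTR13G (0.34), MMSAT4 (-0.11) and ORR1A2 (-0.31). Among genes, Zfp352 rose by 2.80, Zscan4f by 2.14, Zscan4d by 2.07, Zscan4b by 2.02 and Zscan4c by 1.81. Also higher were Vmn2r60 at 1.29, Cd209c at 1.18, Poteg at 1.11, Vmn2r96 at 1.05, Slc22a13 at 1.03, Nat8f2 at 1.00, Rdh16 at 0.82, Clec2g at 0.51 and Mmp1b at 0.50. Among list members and early fallers, Igf2 was at 0.76, Zfp560 at 0.67, Peg10 at 0.62, Fgf5 at 0.59, Pax3 at 0.58, Col5a2 at 0.57, Dazl at 0.56, Edn1 at 0.52, Kynu at 0.49, Zfp37 at 0.43, and Klf6 and Krt18 at 0.36.

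Among genes lower at 48 h than at 24 h, Gli1 was at -1.81, Rasgrp1 at -1.68, Aoah at -1.38, Inhbb at -1.24, Sytl3 at -1.22, Trh at -1.17, Mcf2 at -1.13, Fam196b at -0.92 and Stk33 at -0.76. Hnf4a was at -0.90, Nr0b1 at -0.67, Tfcp2l1 at -0.64, Bcl11a at -0.56, Fgf4 at -0.56, Lama1 at -0.56 and Nodal at -0.46. Lower too were Oas1g (-0.94), Ifitm1 (-0.77), Trib3 (-0.76), Gstm1 (-0.69), Rpl10l (-0.65), Gdf15 (-0.62), Mavs (-0.61), Rpl13a (-0.49), Hist1h2bh (-0.44) and Setdb1 (-0.40). In all, limma called 6569 genes and 34 families between 24 and 48 h. The 6569 genes became 3362 without 24 h replicate 2 and 3224 without 48 h replicate 1, and the 34 families became 53 without 24 h replicate 2 and 22 without 24 h replicate 3. The 10 splits of these 6 libraries are too few for a share under 0.05. The real split gave 6569 genes against at most 3 in another and 34 families against at most 0. Only 1 split, the real one, gave as many calls. Every other split mixes libraries of both times within each group, which widens the spread and lowers the calls. Low counts in other splits thus show little about chance.

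Gene values fell together at 48 h against 0 h, by a median of 0.37 on the log2 scale. The share of recovered reads in genes without Rn45s changed by -0.13 (50.8% at 0 h and 46.4% at 48 h), less than the median fall. The sum of scaled reads over these genes, a measure more like the share, changed by -0.30. Whether repeat transcripts took reads from genes cannot be decided from this share, because the basis of the size factors is not known. The total behind the share may also count reads of Rn45s more than once. Longer genes did not lose more: the longest genes minus the shortest differed by 0.165 (medians of -0.27 and -0.43). One scaling factor per library and a real fall of most transcripts cannot be told apart here, because the spread of medians across genes grouped by mean value was 0.112 (-0.43 to -0.32) and the yeast reads that would separate them are not in the table. A lower output of genes after the compounds were added stays possible and untested.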

How the results depend on the processing

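The edgeR test, the removal of 0 h replicate 2 and 24 h replicate 2 together, the non-coding class, the minimum mean at 0 h alone and the sum without Rn45s were chosen only after the results were seen. The cause of each shift below was not tested unless stated. Changes of about 2-fold in copies were mostly not detectable: in simulated 48 h data 22% of the 2-fold rises of copies were found, against 100% of those of genes. Runs alone were not tested, since the table merges them. A median of copies gives no count of families; it lay beyond the spread of the summed change in 39 of 84 cases. DESeq2 was not run: the plan named limma without the trend in its place for scaled values.

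Rescaling over genes, which takes out the common shift by construction, gave 4677 genes at 12 h and 6638 at 24 h, and 316 families at 24 h, 510 at 48 h and 331 at 48 h versus 24 h. Directions with a call under either scaling flipped for Setdb1 (0.154 at 48 h, 0.151 at 3 h), Suv39h1 (0.278 at 48 h), ORR1A2 (0.168), ID_B1 (0.137), MMSAT4 (0.197) and 7SK (0.015), all 4 at 48 h, and, among sums whose libraries stood apart from those at 0 h, for genes (0.087 at 48 h), all repeat copies (0.032), MMERVK9 (0.028), RLTR13/ERVB4 and RLTR45/44 (0.069), young L1 (0.063) and older L1 (0.011) at 3 h, and SINE B1 (0.048), SINE B4/ID (0.154), minor satellite (0.203) and structural RNA (0.011) at 48 h. Log2 ratios of sums became -0.034 for genes at 3 h, and 0.319 at 12 h and 1.439 at 48 h for all repeat copies. Of 238 changes of named items, 205 kept direction and side of the threshold, 11 without a call under either scaling changed sign, 7 with a call flipped, 4 no longer passed and 11 newly passed. With the minimum at 0 h alone, 142 of 189 MMERVK10C and 47 of 158 IAP copies rose at 48 h.

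A minimum change of 2-fold left 57, 385, 745 and 1455 genes at 3, 12, 24 and 48 h, 200 at 48 h versus 24 h and 1620 over time; 5, 60, 88 and 111 families and 4 at 48 h versus 24 h; and 925, 3750, 5253 and 6449 non-coding units. No filter gave 11 families at 3 h, 8521 and 14604 copies at 24 and 48 h, and 15112 and 19689 non-coding units, since more units were tested. A minimum mean of 50 gave 1065, 1206 and 1368 copies and 2655, 3222 and 4072 non-coding units at 12, 24 and 48 h, since fewer were tested. Without the trend, 1263 genes and 13 families were called at 3 h, and with only the groups compared 6119 genes, 135 families and 11 copies at 3 h. With 0 h replicate 2 and 24 h replicate 2 left out together there were 1404 genes at 3 h, 4376 at 12 h and 3259 at 48 h versus 24 h, and 14 and 53 families at 3 h and 48 h versus 24 h. Without the 10 families with the highest mean, the sum of all repeat copies was at 0.401 at 24 h and 0.470 at 48 h. An estimated correlation left 8 of 34 list calls, and fry gave another direction for stress (adjusted p 0.66) and receptors (0.818) at 3 h, interferon at 12 h (0.797) and histones at 48 h (0.0302). edgeR kept the direction and side of the threshold of all 238 changes of named items.

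A replicate block gave 3230 genes at 3 h (104 up, 3126 down). It changed no call of a named item or list. Across genes, 30 same-number correlations ran from -0.043 to 0.079, with a median of 0.0095, so no pairing was seen gene by gene. Such correlations cannot see a shift common to all genes of a library. Replicate 2 had the highest log2 median ratio over genes at 0, 12, 24 and 48 h (0.182, 0.456, 0.246 and -0.219) and the lowest at 3 h (-0.25). Whether the numbers pair the samples thus stays open.

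Leaving out each library in turn gave 470 to 2993 genes at 3 h, 1194 to 5547 at 12 h, 2156 to 4938 at 24 h, 8117 to 9323 at 48 h, 3224 to 7277 at 48 h versus 24 h and, without each replicate number, 10842 to 12985 over time. Families ranged over 10 to 20, 163 to 374, 168 to 202, 187 to 199 and 22 to 53 for the same 5 comparisons, copies over 292 to 410, 2574 to 3099, 3824 to 4113 and 4592 to 4771, and non-coding units over 1665 to 2258, 5421 to 6025, 7767 to 8671 and 9784 to 10293. Log2 ratios of gene sums ranged over -0.333 to -0.211, 0.049 to 0.206, -0.094 to 0.047 and -0.298 to -0.249, and of repeat sums over -0.237 to -0.151, 0.405 to 0.580, 0.653 to 0.851 and 1.044 to 1.115. Among the changes of named items, 1377 stood, 13 without a call changed sign, 36 no longer passed and 2 newly passed.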

Other observations

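The tests on Cyp1b1 below, and the tests there of the density of LTR copies, of the strand of the counts and of genes with LTR copies on the opposite strand alone, were chosen only after the results were seen. The cytochrome P450 genes that rose at 3 h came down again: Cyp1b1 was at 222 scaled reads at 3 h, 67.2 at 12 h, 88.7 at 24 h and 109 at 48 h, against 35.9 at 0 h, and Cyp1a1 at 134, 16.9, 22.9 and 24.2, against 6.09 (n = 3 each). Fgf5 fell early and partly recovered, with log2 changes of -1.14, -1.67, -1.86 and -1.27 at the 4 times. Mecom (-1.95), Itga10 (-1.78), Egfl6 (-2.27) and Bcl11a (-1.46) were lower at 48 h. Edn1 (-0.34) and Kynu (-0.07) did not pass at 48 h and flipped to 0.02 and 0.29 after rescaling.

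Other genes that rose at 48 h had raised LTR copies at several distances. Clec2g holds an MMETn-int copy on the opposite strand that rose by 3.57 and lies 2881 bp from its start, Mmp1b lies 19578 bp from an RLTR6-int copy that rose by 4.69, and Clec2f 45843 bp from an MMETn-int copy that rose by 3.41. For Bglap3 the nearest was at 294016 bp and for Poteg at 1093463 bp.

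Genes raised at least 2-fold at 48 h lay near raised LTR copies, with an odds ratio of 10.8. The density of all 95522 LTR copies listed, silent ones included, does not account for it. The ratio stayed at 9.86 (Mantel-Haenszel, 95% interval 7.25 to 13.4) across genes grouped by the number of such copies within 20000 bp. The density of the repeat groups that rose most was not tested apart, so regions rich in those copies stay possible. Neighbouring genes can share a copy, so this interval may be too narrow. The counts mostly kept strands apart: in the 5000 bp past the ends of strongly transcribed genes, copies on the gene's strand had a median of 34.6 scaled reads per kb at 0 h and those on the opposite strand 2.4. One transcript counted in both copy and gene would thus mostly need the same strand. The ratio was 5.64 for copies on the opposite strand (15.9 on the same strand) and 5.75 for genes with copies on the opposite strand alone. Copies inside genes on the opposite strand were not left out, and a few reads of a gene that rose greatly could raise a silent copy there. Shared counting is thus not excluded. Among genes with a mean of at least 50 at 0 h, where folds do not rest on low values, the ratio was 10. A candidate explanation is that LTR copies that rose act on genes near them, which stays a hypothesis. Read-through on the same strand may add to part of the genes, and unlisted LTR copies were not counted. The ratios above show nearness only. Genes and copies of the same region that rose together, with neither acting on the other, could give the same ratios. No test here separates these cases, and H3K9 methylation was not measured here.

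Cyp1b1 rose at 3 h, and 3 of 11 other measured members of the aryl hydrocarbon receptor list rose with it (7 after rescaling). From 3 h to 48 h Cyp1b1 fell by 1.02 (-1.02, SE 0.16), which argues against a lasting release from H3K9 methylation as the whole cause of the 3 h level. At 48 h it was still higher than at 0 h by 1.58 (limma adjusted p 1.6e-21), so such a release as part of the cause stays open. A response to the added degradation compounds through the aryl hydrocarbon receptor may explain the rise; the series has no library with the compounds in cells without degron tags, so this was not tested directly.

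For each comparison with 0 h, the 10 splits of the 6 libraries are too few for a share under 0.05, and 1 split, the real one, gave as many calls. Every other split mixes libraries of both times within each group. A difference between the times then widens the spread and lowers the calls, so low counts in other splits show little about chance. The real counts and the highest of the other splits were 2150 and 13 genes at 3 h, 2288 and 0 at 12 h, 2960 and 0 at 24 h, and 10072 and 0 at 48 h. For families they were 27 and 5, 258 and 1, 197 and 0, and 219 and 0, for copies 374 and 20, 3061 and 4, 4282 and 0, and 5175 and 1, and for non-coding units 2485 and 9, 6365 and 0, 8681 and 0, and 10808 and 0. The F test over time called 13812 genes, and 1 of 100 groupings, the real one, gave as many (highest other 11349). This share argues against chance as the source of the F test count. It does not exclude chance, since a regrouping of the same libraries gave 11349 calls. The number of list calls, 34 at the preset correlation, carries little weight: 61 of 100 groupings of the 15 libraries gave as many, with up to 48. Regrouped libraries still differ by time, and lists of genes that move together are called at that correlation. This count therefore cannot tell whether a given list moved by chance.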
